A study of Homo sapiens with 6 samples.

How the data were processed

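DNase-seq, which cuts accessible chromatin with the nuclease DNase I and sequences the released ends, was measured in A549 cells, a human lung adenocarcinoma line. Cells had received 100 nM dexamethasone, a synthetic glucocorticoid that activates the glucocorticoid receptor, or 0.02% ethanol as vehicle, each for 1 h, per the labels. There were 3 libraries per treatment, numbered 1 to 3 in the labels. The labels do not say whether equally numbered or equally treated libraries came from separate cultures, so the spread between these libraries may be technical. P-values of tests on libraries measure only that spread. P-values from draws of regions, from permuted set labels and from Fisher's tests measure scatter over regions within these libraries and hold no spread between libraries. The receptor ChIP-exo and STARR-seq experiments of the same study were not analysed here.

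The deposited data were 6 lists of peaks, 1 per library, in hg19 coordinates. The submitters' processing notes name CASAVA 1.3, Bowtie, bedtools and MACS2 2.1.0, with no settings. Each list numbers its own peaks, so peaks had been called per library and not on pooled libraries as far as the files show. The columns follow the layout that MACS2 writes. In that layout the deposited ratio is the fold enrichment at the summit over the caller's background estimate for that library. The deposited p-value and q-value of each peak are given as −log10, and the lowest −log10 q of a list lay between 2.51 and 2.71. The deposited score followed the −log10 q multiplied by 10, judged from the values, and was not used further. A last column gives the summit as an offset from the peak start. The files give no read counts, so the sequencing depth is unknown and no interval or floor based on reads can be given. An absent peak means that the signal did not pass the caller's threshold, not that the site was closed.

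Because each fold and q belongs to its own list, libraries were compared by whether a peak was called. Peaks of all 6 lists sharing at least 1 bp were merged to regions, and a region counted as called in a library where that library had a peak in it. Dexamethasone-only regions had a peak in 3 of 3 dexamethasone and 0 of 3 ethanol libraries, and ethanol-only regions the reverse. A single region cannot reach p below 0.1 with 3 libraries against 3, so no p-value is given per region. The counts were set beside those of the other sets of 3 libraries out of 6, of which there are 20 in all, so the smallest share a set can reach is 0.05. Measures per library were compared by an exact two-sided permutation test, whose smallest p is 0.1. For the excess of missing peaks by strength the same permutation is only approximate, since the finished values of the libraries were shuffled. The strength of a peak was described by its percentile of −log10 q within its own list, averaged over the libraries that called the region.

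Clustering was measured as the share of regions with another region of the same set within 50 kb, centre to centre. It was compared with 10000 random draws of as many regions from all 6239 regions called in exactly 3 libraries (one-sided), as was the median distance to the nearest region called in all 6 libraries (two-sided). Such a draw permutes membership of the set over these regions, so the resulting p is called a permutation p. The smallest p that these draws can give is 0.0001 one-sided and, as the smaller tail was doubled, 0.0002 two-sided. Benjamini-Hochberg adjustment was made over these 4 tests. The difference between the dexamethasone-only and ethanol-only sets was tested by permuting the set labels over their regions 10000 times, two-sided tests counting absolute differences, so that the smallest p is 0.0001 there. Fisher's exact test (two-sided) was used for shares of regions. Regions are not independent replicates.

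The design, the alternatives and the rule for named regions were fixed before the data were examined. The rule named the 12 dexamethasone-only and the 6 ethanol-only regions with the highest mean percentile. The percentile limit of 50 that separates strong from weaker regions, and the comparison by bands of 25% of each list, were chosen after seeing the data. Motif searches, distances to gene starts and tests of gene lists, which had also been planned, need hg19 sequence or annotation, which was not used here. Those parts were not run, none of the motifs and gene lists fixed in advance was tested, and regions are named by position alone. Positions count from 1.

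The alternatives were a −log10 q of at least 5 for all peaks or for presence alone, lists of one length, joining of summits within 100 bp, a cover of at least 50% of a region, merging across gaps of 100 bp, autosomes only, 50% reciprocal overlap, a 10 kb window, leaving out each library, and a replicate block. The main comparison has no replicate block. No pair of lists was identical, and the highest Jaccard index, shared bases over bases covered by either list, was 70.8%. The code of the merging and clustering steps was checked on simulated data: 200 of 200 regions placed in the dexamethasone lists of the simulated 75293 regions were recovered, and 2 of 40 random sets had a clustering p under 0.05. The placed regions lay apart from other regions and in every dexamethasone list, and the random sets came from the pool of the draws. The check therefore says nothing on missed calls or on peaks close to those of the other treatment. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.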

Results

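Accessible chromatin was mapped by DNase-seq in A549 lung adenocarcinoma cells after 1 h of 100 nM dexamethasone or of 0.02% ethanol, with 3 libraries per treatment. The dexamethasone libraries held 58360, 60646 and 58677 called peaks (replicates 1 to 3) and the ethanol libraries 58281, 60453 and 61344. Read depth is unknown, since the files hold peaks without counts. Peaks spanned 200 to 1952 bp.

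The first comparison asked whether 1 h of dexamethasone altered the overall extent of accessible chromatin. No difference beyond the spread between libraries was seen. The dexamethasone libraries had 59228 ± 1239 peaks (SD, n = 3) and the ethanol libraries 60026 ± 1576 (SD, n = 3; exact two-sided permutation p = 0.7, smallest possible 0.1). Peaks covered 22.8 ± 1.09 Mb with dexamethasone and 22.9 ± 0.66 Mb with ethanol (SD, n = 3 each, exact permutation p = 1). The median peak width was 310.7 ± 3.2 bp and 310 ± 1.7 bp (SD, n = 3 each, exact permutation p = 0.9). Dexamethasone replicate 3 covered the fewest bases, 21.8 Mb, and without it the difference in covered bases changed sign to 0.43 Mb more with dexamethasone, as it did without ethanol replicate 2 (0.093 Mb) and without ethanol replicate 3 (0.061 Mb).

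Most peaks were shared by both treatments. Of 81216 merged regions, 39934 (49.2%) had a peak in all 6 libraries and 15339 (18.9%) in a single library. A library shared on average 84.8% of its peaks with a library of its own treatment and 83.7% with one of the other treatment. The Jaccard index averaged 68.7% over the 6 pairs within a treatment and 67.2% over the 9 pairs between treatments, a difference of 1.49 points. It averaged 69.6% between ethanol libraries and 67.8% between dexamethasone libraries, the latter below the 68.2% between equally numbered libraries of different treatments and above the 66.7% between differently numbered ones. The true split gave the largest difference of the 10 splits of the libraries, and the next gave 0.85 points (exact p = 0.1, the smallest possible). With 1 library left out this rank was lost in 2 of 6 cases: without ethanol replicate 1 the difference was 1.17 points (exact p = 0.4) and without ethanol replicate 2 it was 0.93 points (exact p = 0.2), so other splits were then as large.

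The peaks missing from the other treatment differed with their strength. In the strongest 25% of each list by −log10 q, 0.106 ± 0.052% of dexamethasone peaks (SD, n = 3 libraries) had no overlapping peak in an ethanol library, which was 6 to 29 peaks of 14591 to 15162 for each pair of libraries. The same share was 0.0046 ± 0.0039% between dexamethasone libraries, 0.0058 ± 0.0082% for ethanol peaks sought in dexamethasone libraries and 0.0011 ± 0.0019% between ethanol libraries (SD, n = 3 each). The excess of peaks missing from the other treatment over those missing from the same treatment was 0.101 points for dexamethasone and 0.0047 points for ethanol (approximate two-sided permutation p = 0.1 with n = 3 each, the smallest possible). The permutation shuffled the finished values without redefining own and other treatment. The values of a treatment also share the same lists of the other treatment, so these p-values are not exact. In the weakest 25% the order was the other way round. There, 45.0 ± 2.7% of dexamethasone peaks were missing from an ethanol library and 45.3 ± 3.8% from another dexamethasone library, whereas 47.3 ± 2.8% of ethanol peaks were missing from a dexamethasone library and 43.4 ± 4.1% from another ethanol library (SD, n = 3 each). The corresponding excess was −0.33 points for dexamethasone and 3.90 points for ethanol (approximate permutation p = 0.1 with n = 3 each). In the second weakest band the excess was −0.06 points for dexamethasone and 4.05 points for ethanol (approximate permutation p = 0.1 with n = 3 each). In the weakest band, ethanol replicate 2 peaks were missing at 50.7%, 51.9% and 48.2% from dexamethasone replicates 1 and 3 and ethanol replicate 1, the shorter lists. From the longer lists of dexamethasone replicate 2 and ethanol replicate 3 they were missing at 43.2% and 41.2%. Most of the shorter lists were dexamethasone lists, and length was not separated from treatment in these weaker bands. In the second strongest band it was 0.80 and 0.77 points (approximate permutation p = 1 with n = 3 each).

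**Figure D1:**
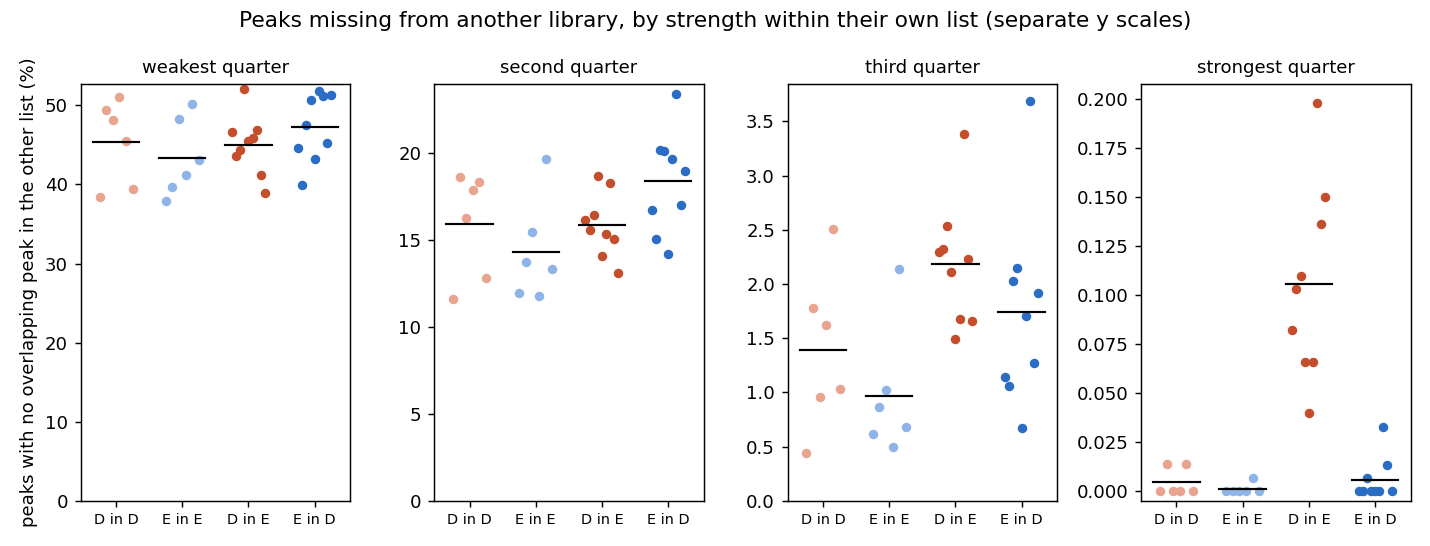
Share of peaks (%, y axis, separate scale per panel) with no overlapping peak in another library, for bands of 25% of each list by −log10 q; D in E is a dexamethasone list searched in an ethanol list and so on, points are ordered pairs of libraries and lines their means. In the strongest band dexamethasone peaks missing from ethanol libraries averaged 0.106%, and in the weakest band all 4 kinds of pair averaged between 43.4% and 47.3%.

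The main comparison asked which sites had a called peak after dexamethasone and none after vehicle. A total of 897 regions (1.10% of all merged regions) had a peak in all 3 dexamethasone libraries and in no ethanol library, and 538 (0.66%) had the reverse pattern. Each of the 18 mixed sets of 3 libraries, taken as the background of regions called in 3 libraries irrespective of treatment, held 118 to 514 regions with a median of 236.5. The dexamethasone set was the largest of the 20 sets, 3.79 times the median mixed set, and the ethanol set the next, 2.28 times that median. The smallest share that a rank among 20 sets can give is 0.05. The ethanol count exceeded the largest mixed set, which joined dexamethasone replicate 3 with ethanol replicates 2 and 3, by a small margin (538 against 514).

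The dexamethasone-only regions included strong sites, which were rare in the other sets. Of the 897 regions, 90 had a mean percentile of −log10 q above 50 within their lists, so that their peaks lay on average in the upper part of the list. None of the 538 ethanol-only regions and 6 of the 4804 regions of the mixed sets did, with at most 2 in any mixed set. Fisher's exact test across regions gave p = 1.07e-19 against the ethanol-only and p = 3.82e-66 against the mixed regions. The percentile limit of 50 was chosen after seeing the data. Both p-values treat regions as independent, which neighbouring regions are not, and hold no spread between libraries. Across the 12 alternatives in which sets were compared, the dexamethasone set held between 84 and 133 such regions. The ethanol set had at most 34 and any other set of like size at most 35, both where summits within 100 bp were joined.

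The excess of dexamethasone-only over ethanol-only regions was 1.67-fold. With 1 library left out it ranged from 1.16 to 1.63-fold in 5 of 6 cases and reversed without ethanol replicate 1, where the counts were 1223 for dexamethasone and 1460 for ethanol. These ratios are not like for like with 1.67. The treatment that lost a library needs fewer peaks for presence, and the other treatment fewer absences. The replicate block, given further below, also reversed the excess (3629 dexamethasone-only against 3902 ethanol-only regions). The block asks for at least 2 of 3 numbered pairs, so its rule is also looser. Whether equal numbers mark pairs is open, so the 1.67-fold excess applies to the unpaired comparison alone. Another set of the same size exceeded the dexamethasone set without dexamethasone replicate 2 (1358 against 1341) and without ethanol replicate 2 (1260 against 1205). The ethanol set was exceeded by another set of its size in 4 of 6 cases: without dexamethasone replicate 2 (1366 against 1057) or 3 (1290 against 1052) and without ethanol replicate 2 (1305 against 1023) or 3 (1116 against 1101). Partly called regions leaned to ethanol: 999 regions were called in 3 dexamethasone and 1 ethanol library and 1411 in the opposite arrangement, and 2583 against 3963 regions were called in 5 libraries with an ethanol or a dexamethasone library missing, respectively. Over all regions, 15976 were called in more dexamethasone than ethanol libraries and 18244 in more ethanol than dexamethasone libraries. The ethanol lists were on average longer (60026 against 59228 peaks), which by itself adds ethanol calls. The lean of partly called regions was not compared with lists of one length.

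**Figure D2:**
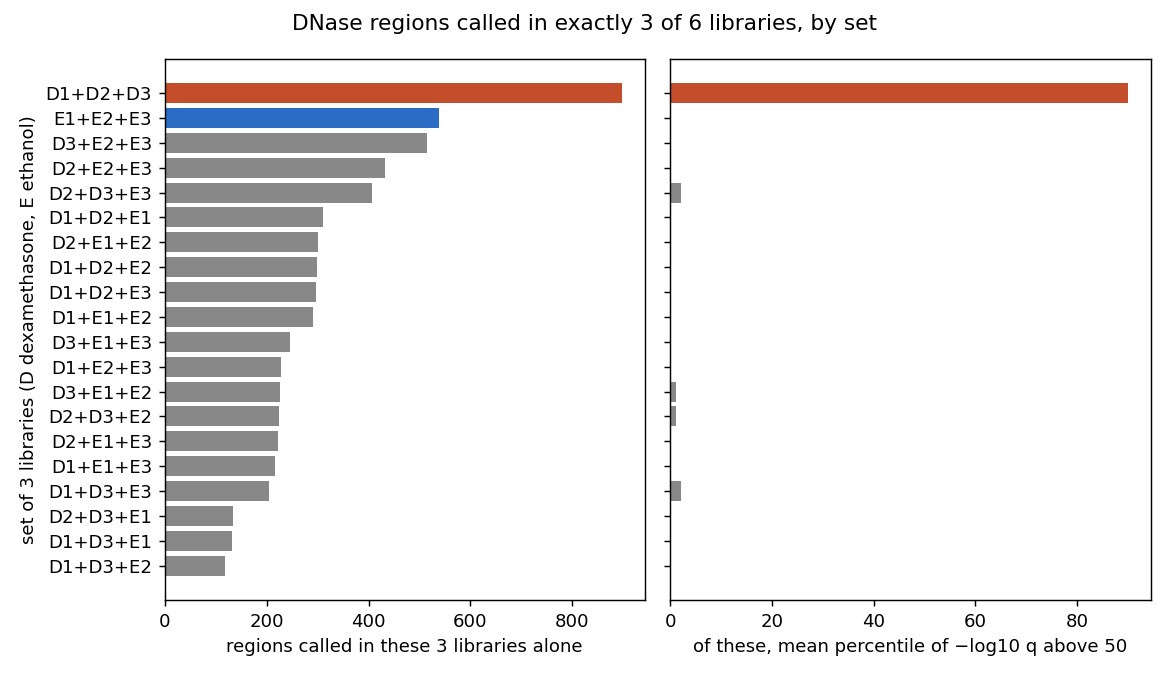
Number of regions called in exactly the 3 libraries named on the y axis (left) and the number of these with a mean percentile of −log10 q above 50 (right); red is the dexamethasone set, blue the ethanol set, grey the mixed sets. The dexamethasone set holds 897 regions, 90 of them above the percentile limit, against 538 and 0 for the ethanol set.

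The strongest dexamethasone-only site lay on chromosome 17 at positions 80091919 to 80092424, with a fold enrichment of 12.7 ± 0.94 (SD, n = 3) and a mean percentile of 86.3. The nearest peak of any ethanol library was 19.2 kb away. Chromosome 17 held 2 further sites of the leading 3, at 46032841 to 46033292 (7.82 ± 1.05-fold, n = 3) and at 1884728 to 1885205 (8.71 ± 0.29-fold, n = 3). They were followed by sites on chromosome 6 at 30894463 to 30894850 (10.6 ± 2.3-fold, n = 3) and on chromosome 16 at 23373774 to 23374378 (10.6 ± 1.4-fold, n = 3). The site on chromosome 16 lay 60.9 kb from the nearest region called in all 6 libraries, the farthest of the 12 named. On chromosome 12, positions 6485110 to 6485751 reached 6.48 ± 0.52-fold (n = 3), but an ethanol peak lay only 0.062 kb away, and the site was no longer called in dexamethasone alone when peaks across gaps of 100 bp were merged. Chromosome 18 carried a site at 21305619 to 21306233 with 11.7 ± 0.58-fold enrichment (n = 3), the second highest fold among the 12. On chromosome 2, sites lay at 10482399 to 10483097 (6.89 ± 0.31-fold, n = 3) and at 102664892 to 102665325 (9.54 ± 1.33-fold, n = 3), with another dexamethasone-only region 47.3 kb and 34.5 kb away. For the first of these, the share of dexamethasone libraries with a peak minus that of ethanol libraries was 0.667 when summits were joined, instead of 1. The remaining sites were on chromosome 20 at 23020351 to 23020979, and on chromosome 5 at 148358456 to 148359038 and 31990858 to 31991307, with fold enrichments of 7.69 ± 0.86, 9.27 ± 1.03 and 8.16 ± 0.94 (SD, n = 3 each). The 12 sites had mean percentiles from 67.9 to 86.3. These folds are the authors' values for single peaks within their own lists.

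The leading ethanol-only sites were weaker within their lists, with mean percentiles from 42.8 to 46.0. The first lay on chromosome 6 at 167200261 to 167200530 with a fold enrichment of 8.51 ± 1.04 (SD, n = 3), 11.3 kb from the nearest dexamethasone peak. The others were on chromosome 10 at 98994213 to 98994510 (8.61 ± 1.75-fold, n = 3), chromosome 7 at 152033911 to 152034164 (7.60 ± 0.44-fold, n = 3) and chromosome 22 at 36938078 to 36938426 (6.53 ± 0.61-fold, n = 3). On chromosome 8, sites at 23075646 to 23075937 (6.54 ± 0.05-fold, n = 3) and at 143111306 to 143111649 (4.99 ± 0.35-fold, n = 3) had a dexamethasone peak 0.50 and 0.66 kb away.

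The series concerns clusters of sites around glucocorticoid receptor binding sites, so the spacing of the changed regions was examined. Dexamethasone-only regions lay near each other more often than other regions called in 3 libraries. Another dexamethasone-only region was found within 50 kb for 133 of 897 (14.8%), against a mean of 6.23% in random draws (central 95% of draws 4.13 to 8.47%; one-sided permutation p = 0.0001, the smallest 10000 draws can give; Benjamini-Hochberg adjusted p = 0.0004 over 4 tests). For ethanol-only regions the figure was 20 of 538 (3.72%), against 3.80% in draws (permutation p = 0.56). The difference between both sets, 11.1 points, was larger than the 3.76 points that their unequal sizes gave under permuted labels (one-sided permutation p = 0.0002). Dexamethasone-only sets thinned to 538 regions still had a share of 9.32% on average.

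Dexamethasone-only regions also lay closer to constitutively called chromatin. Their median distance to the nearest region called in all 6 libraries was 10.2 kb, against 13.8 kb in draws (central 95% of draws 12.2 to 15.3 kb; two-sided permutation p = 0.0002, the smallest 10000 draws can give; adjusted p = 0.0004). Ethanol-only regions lay at a median of 15.4 kb, against 13.8 kb in draws (permutation p = 0.13). Their distance did pass the threshold when a peak had to cover at least 50% of its region (18.3 kb, permutation p = 0.027) and without ethanol replicate 2 (15.3 kb, permutation p = 0.028). It also passed under the replicate block, given further below. The distance turned to the other side of the draws without dexamethasone replicate 1 (12.2 against 12.9 kb, permutation p = 0.28). The median of dexamethasone-only minus that of ethanol-only regions was −5.14 kb (two-sided permutation p = 0.0001 by absolute size, the smallest 10000 permutations can give). For this distance the draws were not matched on strength or width. Dexamethasone-only regions had a median percentile of 24.65 and a median width of 355 bp. The mixed sets had medians of 16.43 to 20.75 and of 269 to 294 bp.

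**Figure D3:**
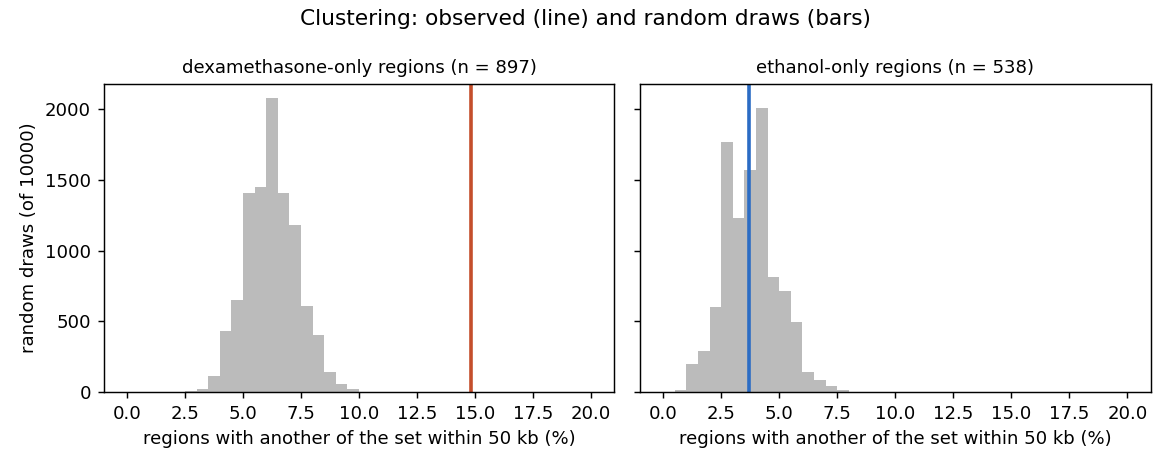
Share of regions with another region of the same set within 50 kb (x axis, %) in the data (coloured line) and in 10000 random draws of as many regions called in exactly 3 libraries (grey bars, number of draws per bin of 0.5 points). The dexamethasone-only share of 14.8% lies above the draws and the ethanol-only share of 3.72% lies among them.

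There were 6 runs of at least 3 dexamethasone-only regions with steps of at most 50 kb, and 0 such runs of ethanol-only regions. The sets differed in size (897 and 538 regions) and runs were not compared with draws, so these counts do not test a difference between treatments. With 1 library left out there were 8 to 18 and 1 to 4 such runs. The largest held 4 regions over 48.4 kb on chromosome 10, from 99474575 to 99522975. It fell to 3 regions in 5 alternatives, among them the merging of peaks across gaps of 100 bp, and was then no longer larger than the others. None of the 4 was above the 50th percentile, and their mean fold enrichments ranged from 2.91 ± 0.53 to 6.01 ± 1.56 (SD, n = 3). Counting 30 kb on either side, 8 of the 16 regions there were called in all 6 libraries. Runs of 3 lay on chromosome 7 at 107875443 to 107949760 and at 134560596 to 134604520, on chromosome 16 at 48199203 to 48238805, on chromosome X at 106917278 to 106991365 and on chromosome 10 at 114092282 to 114121998. The run on chromosome 16 was the only one with 2 members above the 50th percentile. These runs were picked by their number of members after the values were seen.

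**Figure D4:**
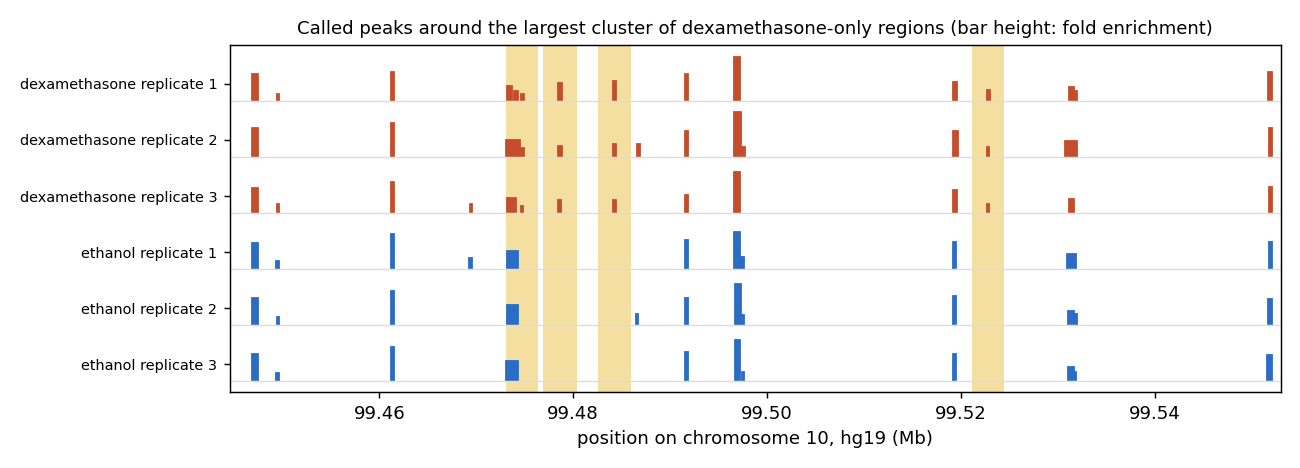
Called peaks in the 6 libraries (rows) around the largest run of dexamethasone-only regions on chromosome 10 (x axis, hg19 position in Mb); bar height is the authors' fold enrichment, on one scale, and bar width the peak. Shading marks the 4 dexamethasone-only regions with 1.5 kb on either side, where the dexamethasone rows have peaks that the ethanol rows lack; the leftmost lies beside a peak called in all 6 libraries.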

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

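The tests that use percentile limits, the joining of regions within 5 kb, the draws matched on distance and the counts of runs were chosen after the results were seen. The share of dexamethasone-only regions with a neighbour and their closeness to regions called in all libraries kept direction and threshold in all alternatives run for them. The ratio of that share to its drawn mean, 2.38, was 1.73 with summits joined, 1.69 to 1.99 without 1 library (shares of 15.2 to 18.1% against draws of 8.14 to 10.7%) and 1.299 under the replicate block (27.5 against 21.1%). Named regions were picked for their calls, so most alternatives could not move them. The overlap within against between treatments kept its sign in all alternatives but not its rank without ethanol replicates 1 or 2, and the design cannot reach a share of splits under 0.05. Leaving out 1 library enlarges counts by construction, with 2 libraries of that treatment instead of 3: dexamethasone-only regions then numbered 1205 to 1716 (1387 without dexamethasone replicate 1, 1716 without 3), ethanol-only regions 926 to 1460, and their ratio ranged from 0.838 to 1.63, below 1 only without ethanol replicate 1. Runs of at least 3 regions then numbered 8 to 18 (dexamethasone-only) and 1 to 4 (ethanol-only). Above the 50th percentile, they then numbered 84 to 115 and 1 to 6; the ethanol-only ones numbered 1 with a −log10 q of at least 5, 1 with lists of one length, 34 with summits joined, 11 with a cover of 50% of the region and 6 under the replicate block. The replicate block (at least 2 of 3 numbered pairs) gave 3629 dexamethasone-only and 3902 ethanol-only regions, a ratio of 0.93, with 83 and 58 runs of at least 3 regions; the other 6 swaps within pairs gave 1902 to 2971. Over the 41282 regions not called in all 6 libraries, deviations of equally numbered libraries correlated with r of 0.09999, 0.05 and 0.09. The limit was 0.1, so the main comparison was left unpaired. Differently numbered pairs all had negative r. For each library the 3 values of r nearly cancelled, so these negative values add no evidence of their own. Whether equal numbers mark pairs stays open. Apart from these counts and ratios, the block changed only the call on the ethanol-only distance to regions called in all libraries, 14.4 kb (permutation p = 0.0008). That distance also passed the threshold with a cover of 50% of the region (18.3 kb, permutation p = 0.027) and ranged from 12.2 to 15.3 kb without 1 library, under the draws only without dexamethasone replicate 1. Ethanol-only clustering, which did not pass the threshold in any alternative, moved to the other side of the drawn mean with a cover of 50% of the region (4.33 against 4.22%), on autosomes (3.84 against 3.83%) and without dexamethasone replicate 1 (7.23 against 5.73%) or 3 (7.03 against 6.94%) or ethanol replicate 1 (9.32 against 8.65%) or 3 (7.72 against 6.70%), with a range of 5.18 to 9.32% without 1 library. The treatment difference in covered bases then ranged from −0.66 to 0.43 Mb and in median width from −0.5 to 2.5 bp; neither passed the threshold. The cause of these shifts was not tested. Depth is unknown, which limits comparisons to called peaks; motif, gene-start and gene-list alternatives were not run.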

Other observations

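The tests of other splits of the libraries, of regions above the 50th percentile, of joined regions, of matched draws and of the clustering of weak regions were chosen after the results were seen, as were the use of the difference between both sets and of their bounds against segments and the lean relative to each set's own level, and the ethanol-only clustering was known before any test of clustering here was set down.

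Against the other regions called in exactly 3 libraries, none of the 24 chromosomes held a different share after adjustment (Fisher's exact test, Benjamini-Hochberg). The smallest p was that of chromosome 16, which held 51 dexamethasone-only regions (5.69%) against 3.44% of the others (Fisher's exact p = 0.0023, adjusted p = 0.054). Among partly called regions that leaned to one treatment, 46.0% of 32785 leaned to dexamethasone. Around the 90 strong dexamethasone-only regions this share was 43.8% of 16 regions within 5 kb, 55.2% of 29 at 5 to 10 kb, 54.6% of 216 at 10 to 50 kb and 47.0% of 215 at 50 to 100 kb, so the first bins rest on few regions.

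The first pattern is the excess of regions called in one treatment alone: the true split gave 1435 such regions and the highest other split 824, the real one being 1 of 10, and 10 splits are too few for a share under 0.05. List length decides nothing: the dexamethasone lists were on average the shorter ones (59228 against 60026 peaks), so the ratio of dexamethasone-only to ethanol-only regions of 1.87 with every list at the length of the shortest is no test of longer dexamethasone lists. Peaks that pass or miss the threshold at random are argued against for the strong part, where the dexamethasone set held 90 regions and no other set over 2. The margin was narrower with summits joined (133 against at most 35) and without dexamethasone replicate 2 (106 against at most 27). For the weak part, at or below the 25th percentile, the dexamethasone set held 458 regions and the next set 374, within the 1.5-fold limit that threshold noise was set to allow in advance, but 9.17% of the 458 had a neighbour within 50 kb against 1.31 to 5.46% in draws of like strength (one-sided permutation p = 0.0001, the smallest possible), which argues against noise as the whole of that part and leaves its share unknown. For both parts, an effect of dexamethasone and a handling difference between treatments that the labels do not record both stay open and untested, since the lists show only whether a caller's threshold was passed.

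The second pattern is the clustering of dexamethasone-only regions. Segments in which weak peaks gather in any library, such as amplified segments of this cell line, are not decided here. The comparison with ethanol-only regions was chosen after their lack of clustering was known. Those regions did not share the pattern: the shares with a neighbour differed by 11.1 points against 3.76 under permuted set labels (one-sided permutation p = 0.0002). The upper exact binomial bound of the ethanol ratio of observed to drawn share, 1.497, lay below the dexamethasone set's lower bound of 2.02. These bounds were computed for the main setting alone, and with 1 library left out the dexamethasone ratio was 1.695 to 1.989. The bound written in advance, a ratio above each other set, was not met, because a mixed set of 135 regions reached 3.04 against 2.38; that set had 4 regions with a neighbour, none of the 19 sets passed the permutation threshold of 0.05, and the binomial bounds treat regions as independent, which neighbours are not. One site called as several regions is argued against by a share of 13.8% after joining regions within 5 kb (draws up to 7.71%). Draws matched on the distance to the nearest region called in all 6 libraries had shares of 4.79 to 9.25%, against 14.8% observed. This argues against closeness to such regions as the source. The number of regions nearby was not matched, so a location in denser accessible chromatin stays open. Gained sites that gather in common domains, as the title of the series proposes for receptor binding sites, remain a candidate explanation that these lists cannot test without receptor binding data.

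Whether weaker gained sites gather around strong ones is the third. Of 807 weaker dexamethasone-only regions, 15 (1.86%) lay within 50 kb of a strong one, above the central 95% of draws from mixed regions (0.25 to 1.36%; one-sided permutation p = 0.0007). However, 8 of 538 ethanol-only regions (1.49%) did so too, and the difference between these sets did not pass the test (Fisher's exact p = 0.67), so the data may reflect where strong sites lie rather than the direction of change. Among partly called regions within 50 kb of a strong site, 54.0% of 261 leaned to dexamethasone, which missed the bound set in advance because another set of 3 libraries gave 59.7%. That set leaned by 58.6% over all regions, so the raw share was a poor bound; relative to each set's own level the dexamethasone set rose by 8.03 points and the next by 5.04, and 1 of 20 sets is a share of 0.05, so this was left open.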
